A study of Arabidopsis thaliana with 16 samples.

How the data were processed

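The data are 16 arrays of the Affymetrix Arabidopsis ATH1 design, hybridised with biotin-labelled RNA from rosette leaves of WT and cmt plants, per the labels. The values used are the deposited signal intensities of the series matrix, which the authors made with the MAS5 algorithm in Affymetrix Expression Console 1.2, per the submitters' processing notes. They are on a linear scale and scaled to a common level: leaving out the highest and lowest 2% of probe sets, the mean signal of each array lay between 500.045 and 500.049. Background correction, probe summary and scaling were therefore the authors' own, and no further scaling was applied before the tests. MAS5 subtracts a mismatch signal, which makes dim probe sets noisy and widens their fold changes, and scaling to a common mean removes any change in the total amount of messenger RNA. The array files themselves and detection calls were not used here. The ratio of 3' to 5' GAPDH control probe sets lay between 3.32 and 4.79 on all arrays.

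The table holds 22810 probe sets, of which 64 controls were left out. Of the other 22746, the platform annotation listed 14016, 13513 with 1 gene and 503 with several, and 8730 were not listed and stay unnamed here. The gene identifiers of 13436 probe sets with 1 gene were found among the RefSeq genes of assembly TAIR10.1, which gave the current symbol, locus and kind of gene, and the platform's own name was kept for the 77 others. The assembly was used for names and chromosomes only. Probe sets of several genes were tested and counted but never named. Probe sets whose identifier marks them as matching several transcripts were kept and are pointed out where named.

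Groups follow genotype, treatment and time in the sample titles. Signals were taken as log2, and a probe set was tested if it exceeded the array's 40th percentile on at least 2 arrays, which left 14929 probe sets for 8061 named genes. That percentile lay between 70.8 and 95.8 and serves as the limit for dim signals. Where all arrays of a group lay below it, a fold change is given as a lower bound, the mean of the brighter group over the mean of the limits (or of the dim signals where higher), all as means of log2 values. Where only some of its arrays did, their number is given and each dim array was set to its limit for the bound. One linear model with a mean for each of the 8 groups was fitted over all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a variance trend), leaving 8 residual degrees of freedom, to which limma's prior added 3.97. Tests were two-sided, adjusted by the Benjamini-Hochberg method over all probe sets of a comparison, and called at an adjusted p under 0.05. The comparisons were irradiated against control within each genotype and time, the average of the genotypes at each time, cmt against WT over all conditions and in controls of each time, the interaction of genotype with irradiation at each time, and the difference of the irradiation effect between the times.

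The design, the naming rule, 23 gene lists with 395 genes and most alternatives were fixed before the data were examined. The rule names CMT3; for each irradiation comparison of 1 genotype and for cmt against WT up to 8 genes with the largest rise and 8 with the largest fall among those that passed without overlap of the arrays (for cmt against WT, in the same direction in all conditions); up to 4 members of each fixed list with the smallest p; and 5 genes with the smallest p for interactions, for the difference between times and where fewer than 5 passed. A gene with several probe sets is given by the brightest. Other genes are said to be chosen after their values were seen. Only 57 of the 395 list genes had a named probe set, and 49 were tested. Lists with at least 3 tested members, 7 in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. A further 20 lists were made after it was known which genes carry names but before any comparison was run, and 19 had enough members. With the estimated correlation no list, fixed or added, passed in any comparison for which lists were tested.

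Alternatives were quantile normalization, an offset of 32 before the log, no filter or one at the 60th percentile, only the arrays compared, no variance trend, array weights, a 2-fold minimum, the replicate number as a term, the estimated correlation, and leaving out each array in turn, after which a lone array is assumed to vary like those of other groups. The array weights came out equal for both arrays of each group, so that alternative reweights whole groups and cannot single out an array. A separate replicate term at each time and the comparison of control leaves by age were added after seeing the data. The labels number the replicates 1 and 2 in each group and the design text names independent experiments, but neither says that a number marks a shared batch or day. Deviations from the group means of same-numbered arrays correlated with r between 0.106 and 0.414 in all 6 pairs of groups at 1 d, so the 1 d results are also given with a replicate block within each time point (1047 in place of 608 probe sets for both genotypes), while at 5 d 3 of 6 pairs exceeded 0.1. The procedure was tested on simulated data with 14929 genes. For the WT comparison at 1 d it recovered 47% of 100 genes changed by 1 on the log2 scale and 84% of those changed by 2, with 12 unchanged genes called. For the average of the genotypes at 1 d the shares were 74% and 97%, with 4 called, for cmt against WT 93% and 99%, with 9 called, and for the difference between times 44% and 88%, with 4 called. With no change simulated, no gene was called (0 in each of 12 comparisons). A simulated list of 4 genes shifted by 1 was called in 19 of 20 runs, and 5 of 120 tests of unshifted lists were called. The simulated noise was independent between genes and between arrays. These rates therefore do not cover correlated list members or deviations shared by same-numbered arrays.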

Results

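Transcript levels were measured on 16 Affymetrix ATH1 arrays, 1 per RNA sample, from rosette leaves of Arabidopsis thaliana Col-0. Plants were wild type (WT) or the mutant labelled cmt, which the design text names cmt3. CMT3 is chromomethylase 3, a DNA methyltransferase that acts mainly at cytosines in CHG context and helps keep transposons silent. Leaves of each genotype were collected from unirradiated controls and from plants given 200 Gy of gamma radiation, 1 d or 5 d after irradiation, at 29 d or 33 d after sowing. This gave 8 groups of 2 arrays, and the labels describe the replicates as separate biological samples, each from leaves pooled over many plants. The deposited MAS5 signal had a median between 150.0 and 171.1 per array, and replicate arrays correlated with r between 0.948 and 0.979 across probe sets, which are not independent replicates. With 2 arrays per group, the number of arrays limits the precision of every comparison. In all, 14929 probe sets were bright enough to be tested, and 8144 of them carry the name of exactly 1 gene. Log2 changes are given with their SE from limma and, unless stated, each group mean rests on 2 arrays. No probe set was named for CMT3 in the annotation used here (0 probe sets), so its level could not be used to check the genotype labels.

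The first question was which leaf genes responded to irradiation in WT at 1 d. Only 39 of the 87 probe sets that were higher carry the name of 1 gene, and the genes below come from these. Unnamed probe sets, picked after their values were seen, had larger fitted rises. One rose by 5.55 ± 0.35 from 59.6 to 2800, with a dim control array (limma adjusted p = 1.85e-05). Another, dim in controls, rose at least 3.92-fold (fitted 7.08 ± 1.39, limma adjusted p = 0.0407). Most of the strongest rises among named genes were those of genes with dim signals in control leaves, so that only a lower bound of the fold change can be given. AT4G22960 rose at least 8.94-fold, from a mean signal of 33.2 to 653 (fitted log2 change 4.297 ± 0.285, limma adjusted p = 1.91e-05), and MSRB9, a methionine sulfoxide reductase, rose at least 11.9-fold, from 62.6 to 871 (3.80 ± 0.30, limma adjusted p = 9.38e-05). AT5G60250, a RING-type zinc finger protein, rose at least 8.61-fold (limma adjusted p = 0.000472), and AT1G26380, a berberine-bridge-like oxidase, rose at least 8.13-fold (limma adjusted p = 0.000285). The receptor-like kinase AT1G51890 and the AAA-type ATPases AT3G28510 and AT3G28580 also passed, with rises of at least 7.72-fold, 3.90-fold and 3.54-fold, and AT3G45730 rose by 3.59 ± 0.62 on the log2 scale to a signal of 3248. Among the genes that fell, PDF1.2, a plant defensin of the jasmonate and ethylene response, fell by 2.49 ± 0.30 from a signal of 2218 to 396 (limma adjusted p = 0.00172). AT5G50335 fell by 1.69 ± 0.29, AT3G15680 by 1.34 ± 0.21 and AT5G24570 by 1.04 ± 0.17. AT2G43550, AT1G62290, UGT76E11 (a UDP-glycosyltransferase) and BGLU16 (a beta-glucosidase) had log2 changes between -0.97 and -0.73.

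In total 103 probe sets passed in WT at 1 d, 87 higher and 16 lower after irradiation. The count was 36 without the irradiated replicate 1 array, 28 without the control replicate 1 array and 27 without the irradiated replicate 2 array, and it was 53 when only the 4 arrays compared were fitted and 188 with array weights. With a replicate block within each time point, added after seeing the data, it was 172, 134 higher and 38 lower, UGT76E11 lost its call (limma adjusted p = 0.0552) and SAG101 passed (limma adjusted p = 0.018). Of 16 genes named above, AT4G22960, MSRB9, AT5G60250, AT1G26380 and PDF1.2 passed in each of the 4 fits that left out 1 array, and the other 11 did not. After quantile normalization AT3G28580, AT1G62290, UGT76E11 and AT3G28510 lost their calls (limma adjusted p = 0.082, 0.0918, 0.136 and 0.143).

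Of the gene lists fixed beforehand, 20 of 23 had at least 1 measured and named gene, 49 genes in all, and 7 lists had the 3 members needed for a set test. In WT at 1 d, 1 of the 49 genes passed over all genes tested, PDF1.2 in the jasmonate list, and 5 higher and 4 lower genes passed when adjusted over the list alone. The senescence list stood out, with all 4 measured members higher: WRKY53 by 1.41 ± 0.75, SAG101 by 1.27 ± 0.32, WRKY6 by 1.08 ± 0.46, and SAG29, whose arrays all lay below the limit for dim signals, so that no size can be given. It passed the camera set test (adjusted p = 0.00106) but not with its own correlation between members (adjusted p = 0.172 with an estimated correlation), and no member passed alone over all genes. SAG101 has a role in senescence and in immunity, WRKY53 and WRKY6 are transcription factors of both processes, and SAG29 is a sugar transporter. The other 6 tested lists did not pass: the smallest of their camera adjusted p was that of the antioxidant enzymes, 0.287. The DNA damage and repair lists had only 3 measured genes. ATMND1, a meiotic recombination factor, was dim in controls and at least 1.61-fold higher after irradiation (limma adjusted p = 0.111), while AT1G48360 had a log2 change of -0.09 ± 0.22 and ATLIG4, the DNA ligase of end joining, one of -0.02 ± 0.18. Flower meristem, root and morning clock genes had no measured member, and the single guard cell gene, FMA, had a log2 change of -0.26 ± 0.27 (limma adjusted p = 0.852).

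The same comparison in cmt at 1 d gave many of the same genes. AT3G28510 rose at least 6.78-fold, from a signal of 3.62 to 538 (limma adjusted p = 0.000916), AT5G60250 at least 7.62-fold, AT4G22960 at least 8.53-fold (limma adjusted p = 3.13e-05) and AT1G51920 at least 2.302-fold. MSRB9 rose from 105 to 1291 (3.61 ± 0.30, limma adjusted p = 0.000117), AT1G51890 at least 7.19-fold, with 1 of 2 control arrays dim, AT3G45730 by 3.72 ± 0.62, and AT2G42360, a RING-type protein, at least 3.07-fold. AT1G78450 fell by 1.68 ± 0.33, AT3G28220 by 1.61 ± 0.28 and AT3G15680 at least 2.41-fold, with 1 of 2 irradiated arrays dim. AT5G63480, AT3G27050, AT2G15830, AT1G62290 and AT2G43550 had log2 changes between -1.19 and -1.02. From the fixed lists, TAPX, the thylakoid ascorbate peroxidase, fell by 0.84 ± 0.16 (limma adjusted p = 0.0275). It was the only one of the 49 list genes that passed over all genes, and 3 higher and 3 lower genes passed when adjusted over the list alone. PDF1.2 had a log2 change of -1.31 ± 0.30 (limma adjusted p = 0.0698), and the senescence list a camera adjusted p of 0.0518.

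In cmt at 1 d 139 probe sets passed, 102 higher and 37 lower. The count was 66 without the irradiated replicate 1 array, 84 without the control replicate 1 array and 62 without the control replicate 2 array, 61 higher and 1 lower. Without the irradiated replicate 2 array the balance turned, with 55 higher and 78 lower of 133. With a replicate block within each time point the count was 252, 172 higher and 80 lower, SAG101 passed (limma adjusted p = 0.0108), and the senescence list passed (camera adjusted p = 0.023; adjusted p = 0.479 with an estimated correlation). AT3G28510, AT1G51920, AT5G60250, AT4G22960, AT1G51890 and MSRB9 passed in each of the 4 fits that left out 1 array, while TAPX passed in 1 of the 4, the one without the irradiated replicate 2 array (highest adjusted p 0.228). AT3G27050 lost its call after quantile normalization (limma adjusted p = 0.067).

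**Figure D1:**
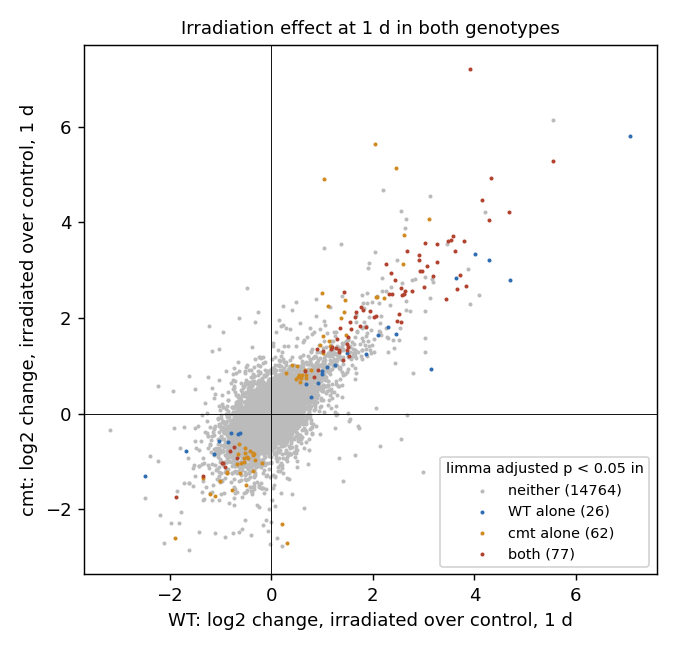
Each point is 1 of the 14929 probe sets tested, with the log2 change after irradiation at 1 d in WT on the horizontal axis and in cmt on the vertical axis, both from 2 against 2 arrays. Colours mark probe sets with a limma adjusted p under 0.05 in both genotypes (77), in WT alone (26) or in cmt alone (62), and all 103 that passed in WT had the same sign in cmt.

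The 2 genotypes share no array at 1 d, so their responses could be compared directly. Of the 87 probe sets that rose in WT and the 102 that rose in cmt, 69 were shared, against 0.594 for independent lists of these sizes. Of the 16 and 37 that fell, 8 were shared, against 0.0397. Across all probe sets the log2 changes of the genotypes correlated with Pearson's r of 0.714 and Spearman's rho of 0.572. Over the 87 that rose in WT the median fitted change was 2.36 in WT and 2.16 in cmt, or 1.87 and 1.995 with groups below the limit for dim signals set to that limit. Whether any response differed between the genotypes was tested with the interaction term, and limma called 0 probe sets, with 187 at an unadjusted p under 0.05 where 746 would be expected by chance. A count that far under chance means that the p-values of this comparison ran high. The lack of calls therefore does not show that the genotypes responded alike. The smallest p-values were those of MYR2, with a response larger in cmt by 1.24 ± 0.27, AT1G51920 with 3.59 ± 0.89, AT2G07000 with -2.97 ± 0.84, AT1G23850 with 1.51 ± 0.43 and AT5G65650 with 0.80 ± 0.23. All of these had a limma adjusted p of 1.00. With dim arrays set to the limit, the differences of AT1G51920, AT2G07000 and AT1G23850 were 0.36, 0.10 and 0.55. The count was 1 without the cmt irradiated replicate 1 array.

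Averaging the genotypes, with 4 irradiated against 4 control arrays of 1 d, brought more of the list genes past the threshold. ATMND1 of the DNA damage list rose at least 1.38-fold (limma adjusted p = 0.0079), and AT2G21640, a marker of mitochondrial oxidative stress, by 1.16 ± 0.24 (limma adjusted p = 0.0172). SAG101 rose from 328 to 818 (1.32 ± 0.22, limma adjusted p = 0.00657), TAPX fell by 0.75 ± 0.11 (limma adjusted p = 0.00284), and PDF1.2 fell by 1.90 ± 0.21 from 1531 to 411 (limma adjusted p = 0.000347). These 3 higher and 2 lower genes were the list genes that passed over all genes, and 3 higher and 6 lower passed when adjusted over the list alone. The one S phase gene, PRL, a subunit of the replication helicase, had a log2 change of -0.83 ± 0.25 (limma adjusted p = 0.0915, or 0.0203 with the replicate block within each time point). The senescence list passed the camera test (adjusted p = 0.00366; adjusted p = 0.247 with an estimated correlation). None of the 4 photosynthesis genes passed, and their log2 changes went from -0.18 ± 0.09 for ATPC1, a subunit of the chloroplast ATP synthase, to -0.03 ± 0.09 for the Rubisco activase RCA.

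Further rises and falls in this average were picked out after their values were seen. AT4G22960 rose at least 8.73-fold (limma adjusted p = 4.56e-07), and MSRB9, with 2 of 4 control arrays dim, at least 12.1-fold, from 81.2 to 1060 (limma adjusted p = 2.41e-06). THI2.2, a thionin, fell at least 3.53-fold, with 3 of 4 irradiated arrays dim (limma adjusted p = 0.00734) and PDF1.2b by 1.64 ± 0.35 (limma adjusted p = 0.0237), on a probe set that can also match related transcripts. AT4G22960, MSRB9, THI2.2, PDF1.2, ATMND1, TAPX and SAG101 passed in all 8 fits that left out 1 array. AT2G21640 passed in 4 of the 8, losing its call without the WT control replicate 1, WT irradiated replicate 2, or either cmt replicate 2 array (highest adjusted p 0.0802). PDF1.2b passed in 3, losing its call without any replicate 1 array or the WT irradiated replicate 2 array (highest adjusted p 0.103).

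In the average of both genotypes at 1 d 608 probe sets passed, 348 higher and 260 lower, of which 211 rose and 48 fell by at least 2-fold. The count was 366 without the cmt irradiated replicate 1 array, 310 without the cmt control replicate 2 array, 294 without the WT irradiated replicate 1 array, 299 without the WT irradiated replicate 2 array and 279 without the WT control replicate 1 array. With a replicate block within each time point it was 1047, 530 higher and 517 lower.

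**Figure D2:**
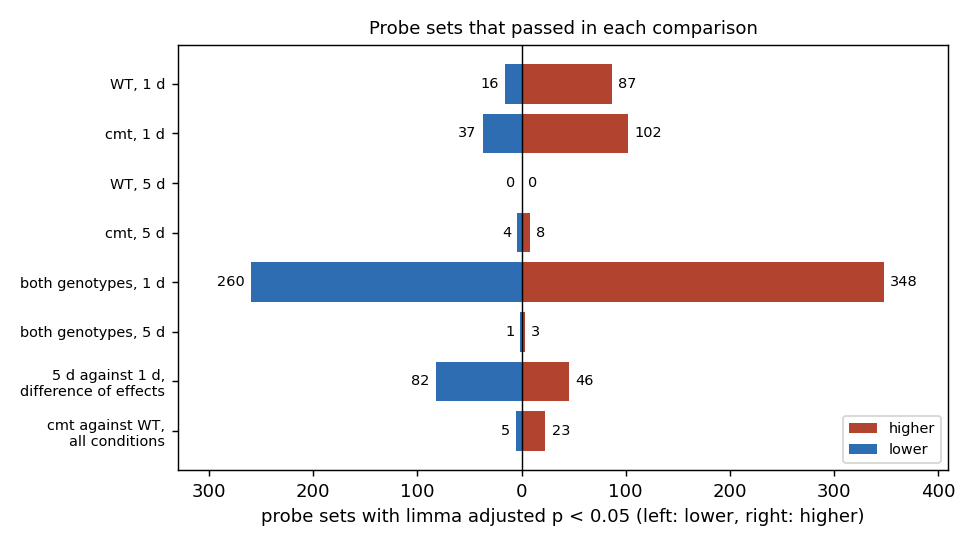
Horizontal bars show how many of the 14929 probe sets passed at a limma adjusted p under 0.05 in the irradiation comparisons, their difference between times and cmt against WT, with those lower to the left of 0 and those higher to the right. Of the comparisons drawn, the average of both genotypes at 1 d had the most, 348 higher and 260 lower, and WT at 5 d had 0 in either direction.

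At 5 d far fewer probe sets passed than at 1 d. In WT no gene passed: limma called 0 probe sets, with 481 at an unadjusted p under 0.05 and 746 expected by chance. With a count under chance, the lack of calls does not show that the WT response was absent. The genes with the smallest p-values were XTH33, a xyloglucan-modifying enzyme of the cell wall, AT4G29200, CHL, AT4G22960 and AT2G34810. CHL had a log2 change of -0.69 ± 0.15, AT2G34810 one of 0.68 ± 0.15, and AT4G22960, dim in controls, was at least 1.71-fold higher, while XTH33 was dim on all 4 arrays and AT4G29200 on 3 of them. All of these had a limma adjusted p of 1.00. None of the 49 list genes passed over all genes, and 0 higher and 2 lower passed when adjusted over the list alone. In this comparison the array labelled WT control 5 d replicate 2 stood between the genotypes at 24 probe sets that separate cmt from WT, at a median of 44.4% of the gap between their mean signals. Without it 2 probe sets passed, without the WT control replicate 1 array 1 passed, and without the WT irradiated replicate 1 array 2 passed.

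In cmt at 5 d 12 probe sets passed, 8 higher and 4 lower. EXO, a gene of brassinosteroid-driven leaf growth, rose from 155 to 1485 (3.26 ± 0.38, limma adjusted p = 0.0108), AT3G19680 by 1.81 ± 0.19 (limma adjusted p = 0.0102) and AT4G37240 by 1.67 ± 0.20 (limma adjusted p = 0.0108). AT1G04770, AT2G37950 and AT3G06070 rose by 1.59 ± 0.25, 1.58 ± 0.25 and 1.48 ± 0.22, while AT5G50335 fell by 1.85 ± 0.29 and AT1G20070 by 1.06 ± 0.16. None of the 49 list genes passed over all genes, and 1 higher and 2 lower passed when adjusted over the list alone. All 5 measured flavonoid and anthocyanin genes were higher, among them UGT78D1 by 0.86 ± 0.58 and DFR, with 1 of 2 control arrays dim, with a camera adjusted p of 0.0597. None of the 8 named genes passed in all 4 fits that left out 1 array. The count was 0 without either irradiated array and 4 without the control replicate 2 array, 6 after quantile normalization or without the filter on dim probe sets, 5 with array weights or the replicate number as a term, 3 without the variance trend, 1 with only the 4 arrays compared and 28 with a replicate block within each time point. AT1G04770, AT2G37950, AT5G50335 and AT1G20070 lost their calls after quantile normalization (highest limma adjusted p 0.0545).

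With the genotypes averaged at 5 d, 4 probe sets passed, 3 higher and 1 lower. The 3 were EXO, which rose by 2.12 ± 0.27, AT4G22960 by at least 1.60-fold and AT3G19680 by 1.01 ± 0.14 (limma adjusted p = 0.0342 for each). AT4G37240 had a log2 change of 0.96 ± 0.14 (limma adjusted p = 0.056) and AT5G50915 one of 1.01 ± 0.16 (limma adjusted p = 0.0764). None of the 49 list genes passed over all genes, and 1 higher and 3 lower passed when adjusted over the list alone. The flavonoid and anthocyanin list passed the camera test (adjusted p = 0.0145; adjusted p = 0.179 with an estimated correlation), with 5 of 5 members higher and a median of 0.54. Without the array labelled WT control 5 d replicate 2, 24 probe sets passed, and they included, chosen after their values were seen, AT3G45730, at least 4.14-fold higher with 2 of 3 control arrays dim, AT5G60250, at least 1.81-fold higher with all 3 dim, and PUB22, a ubiquitin ligase of immune signalling, at least 1.81-fold higher with 2 of 3 control and 1 of 4 irradiated arrays dim. The count was 28 without the cmt control replicate 1 array, 13 higher and 15 lower, 1 without the WT irradiated replicate 2 array, and 0 without the WT control replicate 1, the cmt control replicate 2 or either cmt irradiated array. It was 1 with only the arrays of 5 d, 0 without the variance trend or with array weights, and 32, 18 higher and 14 lower, with a replicate block within each time point.

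The interaction of genotype and irradiation at 5 d gave 0 calls in limma, with 329 probe sets at an unadjusted p under 0.05. As 746 would be expected by chance, the lack of calls does not show equal responses here either. The 5 genes with the smallest p-values had a limma adjusted p of 0.647. Their responses in cmt exceeded those in WT by 1.59 ± 0.27 for AT3G19680, 4.47 ± 0.85 for AT1G50040 (0.45 with dim arrays at the limit), 1.44 ± 0.28 for AT4G37240 and 1.58 ± 0.31 for AT3G06070, with -1.21 ± 0.23 for AT1G20070. The count was 2 without the WT irradiated replicate 1 array.

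The change of the response between 1 d and 5 d was tested as a difference of effects, averaged over the genotypes. MSRB9 had an effect lower at 5 d by a log2 difference of -3.05 ± 0.30 (limma adjusted p = 0.000899), AT4G22960 of -2.68 ± 0.29 (limma adjusted p = 0.00106), AT3G18250 of -3.54 ± 0.39 (limma adjusted p = 0.00128) and AT2G45460 of -2.07 ± 0.18 (limma adjusted p = 0.000383). AT3G28220 moved the other way, with 2.11 ± 0.28 (limma adjusted p = 0.00615). With dim arrays set to the limit, the differences of MSRB9, AT4G22960 and AT3G18250 were -2.97, -2.45 and -3.17. These 5 genes passed in all 16 fits that left out 1 array. Of the 23 genes named for the largest changes in a single genotype at 1 d, 11 had a response that differed between the times, although their choice on the same 1 d arrays favours such a difference. From the fixed lists TAPX alone passed over all genes, with a log2 difference of 0.83 (limma adjusted p = 0.0334), and 4 higher and 2 lower genes passed when adjusted over the list alone. In total 128 probe sets passed, 46 with a higher and 82 with a lower value at 5 d than at 1 d. Over the 87 probe sets that rose in WT at 1 d, the median fitted change at 5 d was 0.35 in WT and 0.59 in cmt, or 0.25 and 0.39 with dim groups at the limit. The count was 79 without the array labelled WT control 5 d replicate 2, with 68 probe sets shared. Of the 1 d arrays it was 70 without WT irradiated replicate 1, 63 without WT irradiated replicate 2, 82 without WT control replicate 1 and 78 without cmt control replicate 2, and of the 5 d arrays 48 without cmt irradiated replicate 1 and 72 without cmt irradiated replicate 2. It was 240, 106 higher and 134 lower, with a replicate block within each time point, and PDF1.2 and EXPA8 passed beside TAPX among the list genes.

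The mutant was compared with WT over all 4 conditions, 8 arrays against 8, to find genes whose level depended on genotype irrespective of irradiation and age. The genes higher in cmt were few and their differences large. QQS, an orphan gene tied to starch content and known to be silenced by DNA methylation, was higher by 2.57 ± 0.11, at a signal of 3556 against 598 (limma adjusted p = 4.33e-07). AT5G26270 was at least 26.8-fold higher, with 6 of 8 WT arrays dim (limma adjusted p = 0.000104), and AT2G04770, a transposon-derived locus of the CACTA family, was at least 3.05-fold higher (limma adjusted p = 0.00011), on a probe set that can also match related transcripts. AT2G04770 and QQS were the 2 measured members of the list of silenced loci, and both passed over all genes and when adjusted over the list alone. AT5G45570 was at least 2.66-fold higher and AT5G03090 at least 1.34-fold higher. The annotated pseudogenes AT3G60170, AT5G26020 and AT2G15510 were dim on all WT arrays but 1, the one labelled WT control 5 d replicate 2, and at least 2.59-fold, 2.71-fold and 1.61-fold higher with dim arrays at the limit, and AT2G05950 was at least 1.997-fold higher. Lower in cmt were AT4G16870, also annotated as a pseudogene, at least 3.44-fold at 94.7 against 333, with 2 of 8 cmt arrays dim (limma adjusted p = 0.000113), and LCR68, of the defensin family, with -0.82 ± 0.11 at 2279 against 4029 (limma adjusted p = 0.00512).

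Of 28 probe sets that passed, 23 were higher and 5 lower in cmt. Among the named genes, 7 of the 18 higher in cmt were annotated as pseudogenes, against 66 of 8033 tested (Fisher's exact test, two-sided, p = 5.4e-11, odds ratio 85.3). Each of these 7 exceeded the limit for dim signals on at most 1 WT array, and so was tested only because of its cmt arrays. Before the filter on dim signals pseudogenes were a larger share, 989 of 13436 matched probe sets. The odds ratio and its p-value therefore overstate the excess over all annotated pseudogenes. None of the 7 tested lists passed. The 5 flavonoid and anthocyanin genes were all higher, with a limma camera adjusted p of 0.0549, as were the 6 heat shock genes, with a limma camera adjusted p of 0.0573. Under a replicate block within each time point, added after seeing the data, both lists passed as higher, and the cell expansion and auxin list, with 0 of 3 genes higher, passed as lower (camera adjusted p = 0.0277 for each). None of the 3 passed with an estimated correlation (adjusted p = 0.216, 0.216 and 0.218). When adjusted over the list alone, 3 of the 49 list genes passed, QQS, AT2G04770 and SAG29. SAG29 was at 138 in cmt, where 4 of 8 arrays were dim, and at 65.8 in WT, where 7 of 8 were (limma adjusted p = 0.127). The array labelled WT control 5 d replicate 2 had signals between the genotypes at many of these genes, for example 2030 for AT5G26270 where the other 7 WT arrays reached at most 174. Without it 36 probe sets passed, 27 of them shared. With a stricter filter on dim probe sets the count was 15. AT5G26020 lost its call in 5 of 16 fits that left out 1 array (cmt irradiated replicate 1 of 1 d, both cmt irradiated arrays of 5 d and both cmt control arrays of 1 d; highest adjusted p 0.0761). AT2G15510 lost its call in all but 4 of the 16, those without a WT control array of 5 d, the WT irradiated replicate 2 array of 5 d or the WT control replicate 2 array of 1 d (highest adjusted p 0.125), and had an adjusted p of 0.058 after quantile normalization.

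**Figure D3:**
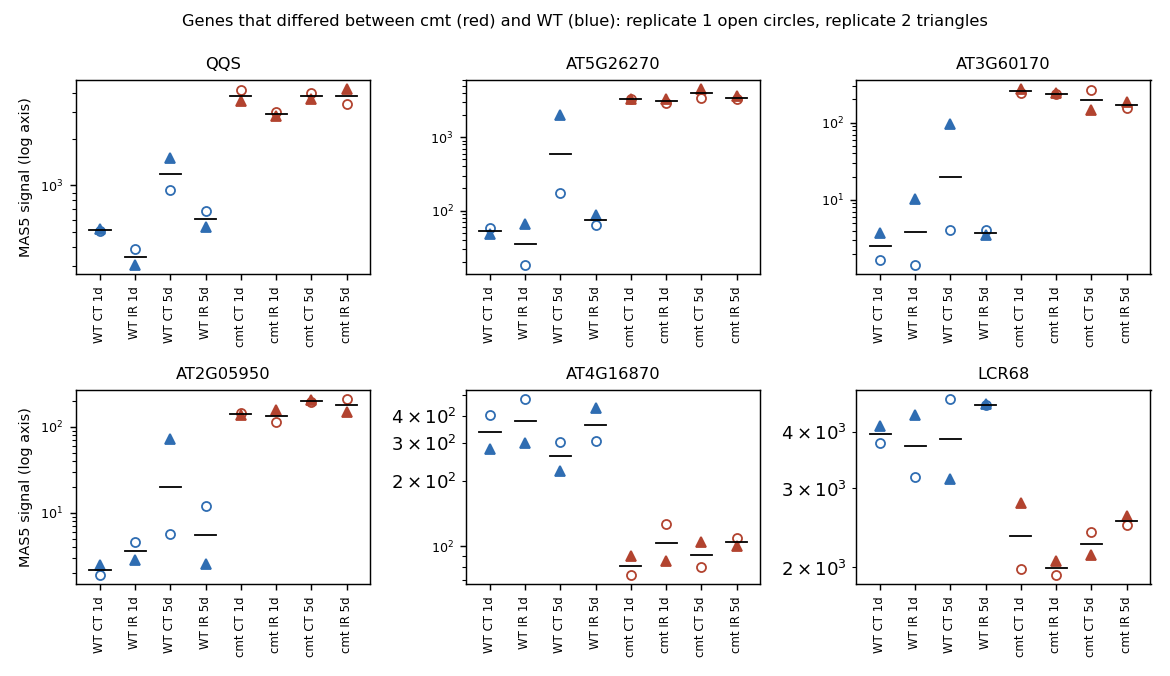
Each panel shows the MAS5 signal of 1 gene on a log axis for the 8 groups, with replicate 1 as open circles, replicate 2 as triangles and the mean of the log values as a bar; WT is blue and cmt red. In 4 of the 6 panels the triangle of WT control 5 d lies well above the other WT points, as for AT5G26270 at 2030 against at most 174.

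In unirradiated leaves of 1 d alone, 7 probe sets differed between the genotypes, 6 higher and 1 lower in cmt. AT5G26270 was at least 46.2-fold higher in cmt (limma adjusted p = 0.0291), AT2G04770 at least 2.82-fold, AT2G15560 at least 3.69-fold and the pseudogene AT2G16000 at least 3.01-fold higher. QQS was higher by 2.89 ± 0.22 (limma adjusted p = 0.000334), and AT4G16870 was lower by a log2 difference of -2.06 ± 0.30 (limma adjusted p = 0.0432). These genes were named after their values were seen, as the naming rule does not cover this comparison. The count was 4 without the cmt replicate 1 array, 2 without the WT replicate 1 array, 1 without the cmt replicate 2 array and 3 without the WT replicate 2 array. It was 3 after quantile normalization or with only the 4 arrays compared, 1 with the stricter filter and 14 without a filter.

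In unirradiated leaves of 5 d limma called 0 probe sets, with 253 at an unadjusted p under 0.05 where 746 would be expected by chance, so the lack of calls does not show equal levels. The QQS signal was higher in cmt by 1.68 (limma adjusted p = 0.109). The 2 WT arrays of this comparison include the one labelled WT control 5 d replicate 2. Without it 4 probe sets passed, among them AT5G26270 with 4.51 ± 0.53 (limma adjusted p = 0.0217) and QQS with 2.03 ± 0.22 (limma adjusted p = 0.0203). Without the cmt replicate 2 array 1 passed.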

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

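Of the tests in this part, the split counts (other than those with a mean for each group or over balanced splits) and the test of control leaves that approach the irradiated level were set up before their results were seen, and all others were chosen afterwards.

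The response to irradiation differed between 1 d and 5 d by the test of the difference itself for 128 probe sets. The log2 difference of the effect, 5 d minus 1 d, was -2.07 for AT2G45460, -3.05 for MSRB9, -2.68 for AT4G22960, -3.54 for AT3G18250 and 2.11 for AT3G28220, and it passed for 11 of the 23 genes named for their change at 1 d. Those 23 were chosen for large effects on the same 1 d arrays, which favours a difference, so that count is no separate support. In a model with this difference beside terms for irradiation, time and genotype, 3 of 100 splits of the 16 arrays, the real one among them, gave as many probe sets as the real 215. Another split gave 1070, and 1241 with a mean for each of the 8 groups in the model, which points to a structure of the samples within the groups. With such a structure the rank of the real split cannot exclude chance.

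Far fewer genes passed at 5 d than at 1 d. A larger spread between replicate arrays at 5 d could hide effects of the same size (the residual SD was 0.371 at 5 d and 0.333 at 1 d). Over the 87 probe sets that rose in WT at 1 d, however, the median cmt effect was 0.586 at 5 d, under the lower quartile of 1.38 at 1 d. For these probe sets that argues against spread as the whole cause. As they were chosen for a rise at 1 d, genes that respond mainly at 5 d could not enter, and the values say nothing about those. Control leaves of 33 d might instead have reached the irradiated level, but the median rise of the cmt control level was 12.7% of the fall of the effect, while the irradiated level was lower at 5 d in 86 of 87. The cmt irradiated level over these probe sets was lower at 5 d by a median log2 change of -1.37 (quartiles -2.015 and -0.836). Whether this decline reflects recovery or leaf age was not tested. At 1 d only the real split of the 35 (1 split) gave as many probe sets, 895 with 202 as the highest other (14 among the 18 splits balanced over the replicate numbers, as the real one is). The split of 202 gave 907 with a mean for each group in the model, which points to a structure of the samples within the groups. With such a structure and so few balanced splits, the first rank of the real split cannot exclude chance. At 5 d the real split gave 0, which all 35 reach by construction (59 as the highest other), so the count decides nothing there.

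Genes higher in cmt were often annotated as pseudogenes, 7 of 18, which cross-matching probe sets could produce. Among probe sets without such a mark, however, 6 of 17 were pseudogenes (odds ratio 91.2, lower 95% limit 26.6). The odds ratio is large partly because pseudogenes too dim to be tested are left out of its baseline. These values argue against cross-matching as the whole cause, although 5 of 23 probe sets higher in cmt carried such a mark against 537 of 14929 tested (Fisher's exact test, two-sided, p = 0.00116). A chromosome segment carried along with the mutation would put these genes together, but chromosome 2, with most of them, held 38.9%, with an upper 95% limit of 64.25% (exact binomial), and chromosome 1, which carries CMT3, held 1 gene. The 38.9% exceeds the 14.5% of tested genes on chromosome 2 (exact binomial p = 0.00994, or 0.0497 when multiplied by the 5 chromosomes). Of the tested pseudogenes, however, 18 of 66 (27.3%) lie there. On chromosome 2 were 5 of the 7 pseudogenes higher in cmt and 2 of the 11 other genes. All tested genes are thus a loose baseline for this set, and a segment there as part of the cause is neither shown nor excluded. Noise of dim probe sets is argued against by the 5 pseudogenes called higher in cmt from the 1 d arrays alone, since in 5 of 5 all 4 cmt arrays of 5 d exceeded the 4 WT arrays of 5 d (lower 95% limit of the share 47.8%, exact binomial), where chance gives 1.43%. A release of silencing in the mutant remains a hypothesis, which was found and tested on the same arrays and for which methylation was not analysed here. In a model with genotype beside a term for each condition, 4 of 100 splits of the 16 arrays, the real one among them, gave as many probe sets as the real 36. The highest other split gave 1593, and 1511 with a mean for each of the 8 groups, which points to a structure of the samples within the groups. With such a structure the rank of the real split cannot exclude chance.

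The array labelled WT control 5 d replicate 2 lay between the genotypes at the genes that separate them, at a median of 44.4% of the gap over 24 probe sets, of which 18 lay between 20% and 80%, while the medians of the other 7 WT arrays lay between -9.85% and 1.05%. A cmt sample with a wrong label is argued against by the upper quartile of 59.4%, and leaf age of 33 d by the medians of the 3 other WT arrays of 5 d, at most 1.05%. Leaves or RNA of both genotypes in 1 sample may explain the values but stay open: the 4 probe sets lower in cmt had a median of 40.9% of the gap (13.1% to 55.4%), and 2 of them, AT4G16870 and LCR68, lay below all 7 other WT arrays (224 against at least 282, and 3149 against at least 3179), while the other 2 lay within their range. A single share of mixing does not account for each gene, since AT2G04770 reached 11.6%, AT2G29920 7.24% and AT4G29200 114%. No biological explanation other than age was tested, and the array keeps its label here.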

How the results depend on the processing

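The separate replicate term at each time and all values for leaf age were chosen after seeing the data. No named gene changed direction where it had passed: of 97 passing values 80 kept their call after quantile normalization, 93 with the offset of 32 and 84 with the replicate block, which ended 13 calls. Most of the 97 values also lost their call in at least 1 of the fits that left out 1 array, more than under any of these alternatives. The smaller number of arrays is built into those fits, but which array was left out mattered too. The cause of the other shifts below was not tested. Counts of probe sets were within 1.5 times the reported ones except as follows. In WT at 1 d (103) only the arrays compared gave 53 and array weights 188. In cmt at 5 d (12) quantile normalization gave 6, no filter 6, only the arrays compared 1, no trend 3 and array weights 5. For both genotypes at 1 d (608) a 2-fold minimum left 259, and at 5 d (4) only the arrays of 5 d gave 1, no trend 0 and array weights 0. For cmt against WT the 60th percentile filter gave 15 in place of 28, and in controls of 1 d (7) quantile normalization gave 3, no filter 14, the stricter filter 1 and only the arrays compared 3. Lists that passed were 2 without a filter and 0 with the estimated correlation in WT at 1 d (1), 2 without a filter and 1 with the offset in WT at 5 d (0), 1 and 1 in cmt at 5 d (0), and 1 without a filter for cmt against WT (0). Leaving out 1 array gave 27 to 120 in WT at 1 d, 62 to 133 in cmt at 1 d, 0 to 2 in WT at 5 d, 0 to 10 in cmt at 5 d, 279 to 565 and 0 to 28 for both genotypes at 1 d and 5 d, 23 to 37 for cmt against WT, 1 to 4 and 0 to 4 in controls of 1 d and 5 d, 0 to 1 and 0 to 2 for the interactions at 1 d and 5 d, 48 to 136 for the difference between times and 824 to 1325 for leaf age (1382). For the lists it gave 1 to 1, 0 to 0, 0 to 2 and 0 to 1 in the 4 single comparisons in the order above, and 0 to 4 for cmt against WT. Under each other alternative limma called 0 probe sets in WT at 5 d, in controls of 5 d and for both interactions.

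Over all groups, deviations of same-numbered samples correlated over 0.1 in 12 of 28 pairs of groups, 6 of 6 at 1 d and 3 of 6 at 5 d. At 5 d the pairs among WT control, WT irradiated and cmt control had r of 0.316, 0.49 and 0.511. The pairs with cmt irradiated leaves had r of -0.336, -0.277 and -0.179. Samples thus also deviated together at 5 d, but there the numbers as labelled do not pair all groups. With the replicate block the count was 5 for cmt at 5 d in place of 12, and 1 list passed in cmt at 1 d in place of 0. The replicate block changed no other count by over 1.5 times (96 in WT and 147 in cmt at 1 d, 620 for both). With a replicate block within each time point, counts were 172 and 252 in WT and cmt at 1 d, 28 in cmt at 5 d, 1047 and 32 for both genotypes at 1 d and 5 d and 240 for the difference between times, with 1 list in cmt at 1 d and 3 for cmt against WT.

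Signal over background limits the dim genes: 28 of the 87 probe sets that rose in WT at 1 d were below the limit on both control arrays, so their size is a bound. CMT3 had no named probe set (0), so its level could not be used to check the genotype labels.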

Other observations

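The comparison of control leaves by age and the added gene lists were chosen after the data had been seen, the lists before any comparison was run. In the average of both genotypes at 1 d, the 6 measured histone genes were all lower after irradiation, and 3 passed over all genes: HTB2 fell by 1.297 ± 0.254 (limma adjusted p = 0.0141), HTB1 by 0.83 ± 0.17 and HTB11 by 0.45 ± 0.10, all histone H2B genes. All 6 passed when adjusted over the list alone, and the list passed the camera test (adjusted p = 9.76e-05; adjusted p = 0.116 with an estimated correlation). The 14 cell cycle genes were all lower too (camera adjusted p = 0.00175; adjusted p = 0.29 with an estimated correlation), among them 3xHMG-box2, a chromosomal protein of dividing cells, which fell at least 1.35-fold (limma adjusted p = 0.00734). All 7 genes of the jasmonate and wound list were lower (camera adjusted p = 0.00698; adjusted p = 0.237 with an estimated correlation), led by the defensins named above. Of 10 defence genes, which include SAG101, WRKY53 and WRKY6 of the senescence list, 8 were higher (camera adjusted p = 0.00244; adjusted p = 0.469 with an estimated correlation), and SAG101 alone passed over all genes. CML41, a calmodulin-like protein from another added list, rose at least 2.12-fold, with 2 of 4 control arrays dim (limma adjusted p = 0.00832). Of 69 plastid-encoded genes 7 were higher, and the median over all 69 was -0.17 (camera adjusted p = 0.000222; adjusted p = 0.491 with an estimated correlation). That list passed in cmt, with a median of -0.27 (camera adjusted p = 3.27e-08; adjusted p = 0.637 with an estimated correlation), and not in WT, with 19 of 69 higher and a median of -0.08 (camera adjusted p = 0.402), and the defence list passed in WT, with 10 of 10 higher (camera adjusted p = 9.43e-05; adjusted p = 0.411 with an estimated correlation), and not in cmt, with 8 of 10 (camera adjusted p = 0.141). The jasmonate and wound list passed in WT (camera adjusted p = 0.00359, and 0.151 with an estimated correlation). In cmt it did not pass (camera adjusted p = 0.0535), except with the replicate block within each time point (camera adjusted p = 0.0453, and 0.334 with an estimated correlation). Whether the genotypes differ was not tested for these lists. Of 17 nuclear photosynthesis genes 15 were lower (camera adjusted p = 0.021; adjusted p = 0.469 with an estimated correlation, and 0.083 after quantile normalization), with camera adjusted p = 0.0728 in WT and 0.0432 in cmt, the latter with adjusted p = 0.653 with an estimated correlation. NdhS, a subunit of the chloroplast NDH complex, fell by 0.62 ± 0.16 (limma adjusted p = 0.0487) but passed in 0 of the 8 fits without 1 array (highest adjusted p 0.181) and not after quantile normalization (limma adjusted p = 0.0521), and the other 16 did not pass. Under a replicate block within each time point, with 1047 probe sets passing, 4 histone, 3 cell cycle and 2 nuclear photosynthesis genes passed as lower in place of 3, 1 and 1, among them HON4 (limma adjusted p = 0.0422) and PRK (limma adjusted p = 0.0401). The list of 15 DNA repair genes did not move as a set (camera adjusted p = 0.761). HTB2 lost its call without the cmt irradiated replicate 1, WT irradiated replicate 1 or cmt control replicate 2 array (highest adjusted p 0.0683), HTB1 passed in 3 and HTB11 in 0 of the 8 fits without 1 array (highest adjusted p 0.0773 and 0.123), and 3xHMG-box2 and CML41 passed in all 8.

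In cmt against WT, the 66 pseudogenes measured were mostly higher, 49 of 66, with 7 passing as higher and 1 as lower (camera adjusted p = 3.1e-09, and 0.194 with an estimated correlation). A pseudogene dim on all WT arrays was among the 66 only if it was bright in cmt, so the count does not describe pseudogenes in general. Of 16 chaperone genes 12 were higher (camera adjusted p = 0.0294, and 0.36 with an estimated correlation). In WT at 5 d, 13 of 16 expansin and xyloglucan-modifying genes were higher after irradiation, with a median of 0.70 (camera adjusted p = 1.71e-06; adjusted p = 0.166 with an estimated correlation), in a comparison that uses the array labelled WT control 5 d replicate 2. Without that array 12 of 16 were higher, with a median of 0.83 (camera adjusted p = 1.79e-06; adjusted p = 0.118 with an estimated correlation), a check added after seeing the data. In cmt at 5 d 10 of 16 were higher, with a median of 0.08 (camera adjusted p = 0.386), and whether the genotypes differ was not tested for this list. All 10 defence genes were higher in cmt at 5 d, with a median of 1.12 (camera adjusted p = 1.03e-05; adjusted p = 0.879 with an estimated correlation). In WT at 5 d 7 of the 10 were higher, with a median of 0.47 (camera adjusted p = 0.0985), and without the array labelled WT control 5 d replicate 2 all 10 were (camera adjusted p = 5.73e-08; adjusted p = 0.233 with an estimated correlation). In the average of both genotypes all 10 were higher (camera adjusted p = 3.2e-05, and 0.984 with an estimated correlation). The jasmonate and wound list did not pass in WT at 5 d (camera adjusted p = 0.465). Without the array labelled WT control 5 d replicate 2, its median was 0.79, with 5 of 7 higher. For the difference between times, 5 added lists passed with effects higher at 5 d. Camera adjusted p was 0.000112 for plastid-encoded, 0.000214 for jasmonate and wound, 0.000214 for histone, 0.0149 for nuclear photosynthesis and 0.0216 for cell cycle genes. None passed with an estimated correlation.

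Control leaves of 33 d differed from those of 29 d at 1382 probe sets, 749 higher and 633 lower, with 4 arrays at each age. Age coincides with the time of collection in this design, so effects of age and of collection cannot be told apart. EXO fell from 6608 to 168 (a log2 change of -5.29 ± 0.27, limma adjusted p = 8.15e-07), the expansin-like EXLA1 by 3.84 ± 0.52 and XTH18 at least 3.56-fold, with 3 of 4 arrays of 33 d dim, all chosen after their values were seen. The expansin and xyloglucan list as a whole had 9 of 16 higher and 7 lower (median 0.16, camera adjusted p = 0.459), with 4 passing as higher and 6 as lower. SAG29, a sugar transporter of senescing leaves, rose at least 2.86-fold (limma adjusted p = 0.000702) and JAL23, a jacalin-related lectin, at least 2.32-fold. Without the array labelled WT control 5 d replicate 2 the count was 1276, with 1045 probe sets shared, and EXO had a change of -5.50 ± 0.28. The count was 824 without the cmt replicate 1 array of 1 d and 844 without the WT replicate 1 array of 5 d. In a model of the 8 control arrays with age alone, only the real split of 35 (1 split) gave as many probe sets, 1365 with 297 as the highest other. The 297 came from the 18 splits balanced over the replicate numbers, as the real one is, and the 17 others gave at most 0. The split of 297 gave 706 with a mean for each group in the model, which points to a structure of the samples within the groups. With such a structure and so few balanced splits, the first rank of the real split cannot exclude chance.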
